A study of Mus musculus with 14 samples.

How the data were processed

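RNA sequencing was applied to ovaries of female wild-type C57BL/6J mice that had or had not received dextran sulfate sodium (DSS), a polymer given to mice to inflame the colon. The labels place 14 libraries in 4 groups: 3 control and 4 DSS libraries at day 7, and 3 control and 4 DSS libraries at day 89. The series text calls the first time the end of modelling and the second a rest of 89 days, and the labels write only the day. Each library carries its own number and no number recurs between groups, so no samples were paired. The labels name the tissue ovary, while the extract protocol in the labels speaks of retinas. Of 16 retina markers in the table the highest FPKM in any library was 7.22, for Rom1, and no other marker exceeded 0.733. Nothing in the labels says whether each library came from a separate animal, so the p-values measure the spread between these libraries, which may be partly technical.

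The authors deposited FPKM values (fragments per kilobase of gene, scaled to sequencing depth), 1 column per library, for 56748 annotated genes, with a gene length for each gene. Per the labels' protocols, libraries were made from total RNA with a TruSeq kit. Per the submitters' processing notes, HISAT2 2.0.5 and the mouse build GRCm38 were used. The counter, the annotation release, strand handling and the treatment of multiply mapped reads are not given in the sources used here. Genes with near-identical copies are therefore uncertain in the split of their reads. Among the genes named, this holds for the alpha globins Hba-a1 and Hba-a2, the interferon-induced families, the immunoglobulin genes, the small RNA genes and the copies that share the symbols 5S_rRNA and U1. Overlapping and antisense genes are uncertain for the same reason.

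In every column, FPKM multiplied by the deposited gene length fell on whole multiples of 1 step, within 0.01 of a step for 100% of values below 300 steps. The step gave the reads behind each value. Recovered totals ran from 15.26 to 18.51 per library in units of 1000000 reads, so depth differed little between groups. The total that the authors' scaling implies was 0.852 to 1.07 times the recovered total, so the deposited values carry a further factor per library. FPKM divides out gene length and depth but not composition. A library in which mitochondrial transcripts take more of the reads would have lower FPKM for the remaining genes, were it not for the further factor. That factor was lowest in the 3 libraries with the highest mitochondrial share (0.852, 0.913 and 0.935, against 0.995 to 1.073 in the others). A lower implied total raises FPKM, so the factor acted against this loss.

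The deposited gene positions differed from the GENCODE M21 annotation of GRCm38: of 52073 gene IDs found in it, 1435 had the same chromosome, start and end. Positions given here come from that annotation on GRCm38, matched by gene ID, and not from the deposited table. Whether the gene models behind the FPKM values differ from that annotation too is not given in the sources used here.

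FPKM values were tested as log2(FPKM + 1). A gene was tested when at least 3 libraries reached an FPKM of 0.5, which left 18006 genes. A gene can pass this filter through the libraries of 1 group alone, which favours genes that are high in that group. limma 3.58.1 in R 4.3.3 fitted 1 mean per group to all 14 libraries, with a mean-dependent prior variance (limma-trend), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. The design was written for a count test should counts be in the table. Because the table held FPKM, the limma test written for that case was used. The comparisons were DSS against control at each day, day 89 against day 7 within each treatment, and the difference between both DSS effects.

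Before the data were examined, 37 gene lists, the rule for genes to be named and a first set of alternatives were fixed. The lists covered pathways, ovarian cell types, immune cells and other tissues. Of these, 36 had at least 3 tested members; the retina list did not. Each list was tested with camera, a test in limma of whether a list's genes rank differently from the other genes, with a preset correlation between genes of 0.01. Adjusted p-values are over the 36 lists of a comparison. The same test with a correlation estimated from the data, and the rotation test fry, stand beside it. fry tests a list against no change and not against the other genes, so its result is not a second test of the same question. Members were counted as changed over all genes tested and adjusted over the list alone.

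For each DSS comparison the genes named were the 10 largest rises and falls past the threshold, with a mean FPKM of at least 1 in a group and no overlap of libraries, leaving out predicted and unnamed genes. Where fewer than 5 passed in a direction, the 5 smallest p-values took their place. Up to 3 members of each described list were added by smallest p. For the other comparisons the number was 5 per direction and up to 2 members of a list. Genes named outside the rule are said to be so. Values of some genes that the rule or the lists cover are not reported here.

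The whole procedure was tested on simulated data with 200 genes changed among 18006. At a true 2-fold change it recovered 29% of the genes for DSS against control at day 7, and 44% at day 89. At a true 4-fold change it recovered 75% at day 7 and 84% at day 89. Recovery in controls between days was 40% at 2-fold and 85% at 4-fold. In DSS between days it was 53% and 82%. Every recovered gene had the right direction, and the false calls numbered 6 for DSS against control at day 7 and 12 at day 89. Changes of 2-fold in the DSS comparisons were thus often missed in the simulation. It drew each gene independently, with no differences shared by the genes of a library, and changed only genes above a floor of mean reads. The real libraries share such differences: a split of the day 7 samples other than the real one called 1615 genes. The simulated recovery and false calls therefore may not hold for these libraries.

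Alternatives tried were another normalization, other filters and pseudocount, only the compared samples, sample weights, the luteal list as a covariate, stricter thresholds and leaving out each sample. After the data had been seen, others were added for mitochondrial share, erythrocyte level, gene length, GC content and the recovered reads. GC content was available for 17366 of the 18006 genes (96.4%). Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.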

Results

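The ovarian transcriptome was measured in 14 libraries: control day 7 (n = 3), DSS day 7 (n = 4), control day 89 (n = 3) and DSS day 89 (n = 4). Dextran sulfate sodium (DSS) damages the colonic lining and is a standard means of producing colitis in mice. The design asks how the ovary differs between DSS and control mice at the end of the model, and whether any difference is present after a long rest. Recovered depth averaged, in units of 1000000 reads per library, 16.6 ± 1.69 in control day 7, 17.1 ± 0.94 in DSS day 7, 17.3 ± 1.09 in control day 89 and 16.2 ± 0.795 in DSS day 89 (SD). A gene near 0.5 FPKM rests on few reads at this depth.

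The libraries also differed in mitochondrial share, gene length trend and globin level. Mitochondrially encoded transcripts took 9.96% and 12.2% of reads in control day 7 replicates 10 and 53 and 14.2% in DSS day 7 replicate 75. In the other 11 libraries the share lay between 0.479% and 4.04%. No label explains these 3 libraries. For the length trend each gene was centred on its mean over all 14 libraries, so 0 is the average library. Relative to that average, short genes stood above long genes at day 7, with a mean log2 difference of 0.249 ± 0.106 in controls and 0.224 ± 0.08 in DSS (SD, n = 3 and 4). At day 89 it was −0.309 ± 0.0227 in controls and −0.185 ± 0.212 in DSS, where replicate R38 alone was positive (0.13). Summed globin FPKM, a measure of red blood cells in the tissue, was 154 ± 137 in control and 538 ± 131 in DSS ovaries at day 7, with every DSS library above every control. At day 89 it was 43.1 ± 0.987 and 255 ± 270.

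**Figure D1:**
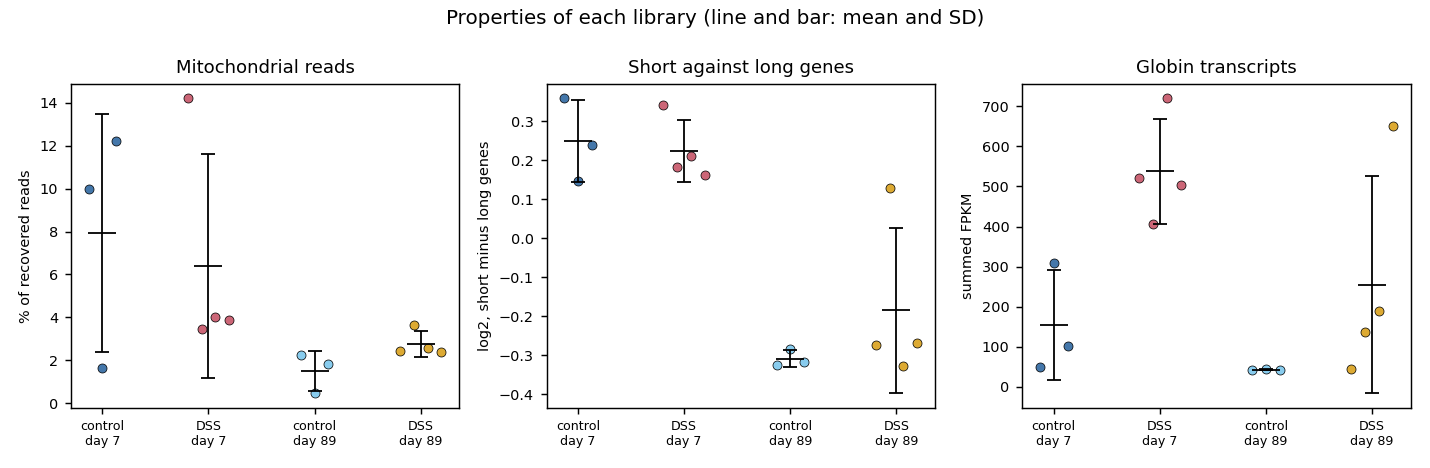
Share of reads from mitochondrially encoded genes (%), level of short relative to long genes (log2) and summed globin FPKM in each of the 14 libraries, by group. Points are libraries and bars the mean and SD. Control day 7 replicates 10 and 53 and DSS day 7 replicate 75 held the highest mitochondrial shares, and the length measure changed sign between days except in DSS day 89 replicate R38. The sign of the length measure is relative to the mean of all 14 libraries, on which each gene was centred.

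At day 7, neutrophil transcripts stood higher in the ovaries of DSS mice. S100a8 and S100a9 encode both subunits of calprotectin, a protein abundant in neutrophils. S100a8 averaged 14.6 ± 17.9 FPKM in DSS (SD, n = 4) and 0.286 ± 0.182 in controls (n = 3), a log2 fold change of 3.03 (SE 0.51). S100a9 averaged 21.7 ± 28.1 against 0.321 ± 0.555, a log2 fold change of 3.50 (SE 0.63). Retnlg, a resistin-like gene of neutrophils, was listed at 0 in all 3 controls and at 22.4, 3.16, 2.14 and 0.443 FPKM in DSS. All 4 DSS libraries exceeded all 3 controls for each of these genes, and DSS replicate 75 was by far the highest, at 41.4 FPKM for S100a8. Their adjusted p over all genes was 0.0638, 0.0777 and 0.139 with limma, short of the threshold. All 3 rose when adjusted over the list alone, out of 7 measured neutrophil genes of 14 listed. S100a8 and Retnlg reached 0.5 FPKM only in DSS day 7 libraries, so they were tested only because they were high there. As a list the neutrophil genes rose by a mean of 1.31 and a median of 0.66 (camera adjusted p = 0.00373; adjusted p = 0.292 with an estimated correlation). The list's mean and p-values thus rest partly on members selected by this difference. Within the 3 libraries of high mitochondrial share the list differed by 2.31 (1 DSS and 2 control libraries), and within the others by 1.00 (3 DSS and 1 control library).

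Acute-phase and antimicrobial genes, which include calprotectin, rose as a list by a mean of 0.68 but a median of 0.33 (adjusted p = 0.0174; adjusted p = 0.378 with an estimated correlation), and 4 of 11 rose when adjusted over the list alone. Of 22 genes listed only these 11 passed the filter, S100a8 among them. Lrg1, a secreted acute-phase glycoprotein, averaged 5.76 ± 2.16 FPKM against 1.64 ± 0.568, a log2 fold change of 1.32 (SE 0.23, adjusted p = 0.0638 over all genes). The macrophage list rose by a mean of 0.45, with 15 of 17 members above 0 (adjusted p = 0.000109; adjusted p = 0.292 with an estimated correlation). Cd68, a lysosomal protein of macrophages, stood at 19.2 ± 3.17 against 6.16 ± 3.91 FPKM. It was the only member to rise when adjusted over the list alone. The complement list rose by a mean of 0.44 (adjusted p = 0.00373; adjusted p = 0.378 with an estimated correlation). Its C1qb, C1qc and C4b, components of the classical pathway, rose when adjusted over the list alone, with log2 fold changes of 1.40, 1.22 and 1.41. The B and plasma cell list rose by 0.56, all 10 members above 0 (adjusted p = 0.0119; adjusted p = 0.292 with an estimated correlation). Inflammatory cytokines and chemokines, of which 10 of 20 listed were measured, rose by 0.53 (adjusted p = 0.0306; adjusted p = 0.354 with an estimated correlation). Among them Ccl2, a monocyte attractant, stood at 4.31 ± 2.84 against 0.842 ± 0.287 FPKM, but DSS replicate 75 lay at 0.848, within the control range. The list differed by 0.05 within the 3 libraries of high mitochondrial share and by 0.64 within the others. The erythrocyte list rose in the same comparison by 1.48, with 6 of 7 members risen when adjusted over the list alone (adjusted p = 6.82e-05; adjusted p = 0.292 with an estimated correlation). T and NK cell genes differed by a mean of 0.11 (adjusted p = 0.454).

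Interferon-response genes went the other way at day 7. The list fell by 0.38, with 21 of 24 members below 0 and 5 fallen when adjusted over the list alone (adjusted p = 1.49e-05; adjusted p = 0.342 with an estimated correlation). Gbp3, an interferon-induced GTPase, stood at 6.12 ± 1.53 FPKM in DSS and 13.4 ± 0.52 in controls. Ifi27 stood at 84.7 ± 10.6 against 160 ± 24.7. The list differed by −0.42 within the libraries of high mitochondrial share and by −0.34 within the others. With the erythrocyte level, which separates the day 7 groups fully, in the model it differed by −0.18 (adjusted p = 0.0934).

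Steroidogenic transcripts were lower in DSS ovaries at day 7. Star encodes the protein that carries cholesterol into mitochondria for steroid synthesis. It averaged 39.2 ± 3.96 FPKM in DSS and 158 ± 66.6 in controls, a log2 fold change of −1.91 (SE 0.43, limma adjusted p = 0.0885). Its level was lower in all 4 DSS libraries than in any control, and the log2 difference was −1.93 within the libraries of high mitochondrial share and −1.74 within the others. The steroid and cholesterol synthesis list fell by 0.63, with 17 of 19 members below 0 and 6 fallen when adjusted over the list alone (adjusted p = 2.41e-05; adjusted p = 0.378 with an estimated correlation). These included Hmgcs1 (log2 fold change −1.45, SE 0.44) and Fdft1 (−0.77, SE 0.24), enzymes of the sterol pathway. Luteal cell genes fell by 0.57 as a list (adjusted p = 0.0194; adjusted p = 0.322 with an estimated correlation), and of its 16 members Star alone fell when adjusted over the list alone. Cyp11a1, which makes pregnenolone, showed 1020 FPKM in DSS replicate 75, above the controls, and 211 to 399 in the other 3. The luteal list differed by −0.10 within the libraries of high mitochondrial share and by −0.90 within the others. Genes of theca and interstitial cells had a mean of −0.45 (adjusted p = 0.073).

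Oocyte genes stood higher in DSS ovaries at day 7: all 23 members were above 0 and the list rose by a mean of 0.63 (adjusted p = 2.41e-05; adjusted p = 0.448 with an estimated correlation), though no member passed, even when adjusted over the list alone. Zp3 and Zp1, which encode proteins of the zona pellucida, had log2 fold changes of 1.28 (SE 0.44) and 1.48 (SE 0.44). Proliferation genes rose by 0.33, 21 of 22 above 0 (adjusted p = 0.00111; adjusted p = 0.528 with an estimated correlation). Ccnb1, a mitotic cyclin, stood at 10.9 ± 2.98 against 4.74 ± 1.73 FPKM. With the luteal level in the model the oocyte list differed by 0.15 (adjusted p = 0.25), the proliferation list by 0 (adjusted p = 0.837) and the sterol list by −0.18 (adjusted p = 0.0966). Centred over the libraries, the luteal level separated the day 7 groups fully, at −0.285 to 0.136 in controls and −0.97 to −0.289 in DSS. It is thus confounded with DSS, and a call lost with it does not show a cause. Granulosa cell genes had a mean of 0.02 (adjusted p = 0.651), and genes of the primordial follicle reserve 0.16 (adjusted p = 0.426). Extracellular matrix genes rose by 0.26 (adjusted p = 0.0119; adjusted p = 0.292 with an estimated correlation) and fasting genes by 0.36 (adjusted p = 0.00227; adjusted p = 0.292 with an estimated correlation). Circadian clock genes fell by 0.18 (adjusted p = 0.0439; adjusted p = 0.292 with an estimated correlation). With the luteal level in the model the fasting list differed by 0.13 and the circadian list by −0.13 (adjusted p = 0.105 for each), and neither was called.

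Within the libraries of high mitochondrial share and within the others, in that order, the remaining day 7 lists differed by −0.27 and 0.49 (proliferation, of opposite sign), 0.29 and 1.04 (oocytes) and −0.48 and −0.88 (sterol synthesis). The values were 1.43 and 0.48 for acute-phase genes, 0.45 and 0.46 for macrophages, 0.33 and 0.67 for complement, and 0.28 and 0.97 for B and plasma cells. They were 1.80 and 0.69 for erythrocytes, 0.23 and 0.30 for matrix, 0.19 and 0.43 for fasting, and −0.17 and −0.14 for circadian clock genes.

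The day 7 calls of many lists depended on single libraries or settings. The acute-phase list was not called with only the compared samples in the fit (0.68, adjusted p = 0.07) or with voom (1.17, 0.0538), nor inflammatory cytokines when scaled to each library's own read total (0.59, 0.0529). Without control replicate 10 the acute-phase list (mean 0.58, adjusted p = 0.0993), inflammatory cytokines (0.51, 0.0993) and the circadian list (−0.12, 0.18) were not called. Without control replicate 51 the B and plasma cell list (0.37, 0.0778) and the luteal list (−0.46, 0.085) were not called, and without control replicate 53 matrix genes (0.22, 0.0641). Without DSS replicate 75 the acute-phase list differed by 0.43 and the proliferation list by 0.54, both called. Inflammatory cytokines were also not called without DSS replicate 81 (0.46, 0.0522), and circadian genes without DSS replicate 75 (0.0755), 81 (0.0561) or 82 (0.0679). Without the 3 libraries of high mitochondrial share, which leaves 1 control at day 7, 6 of the 15 lists kept their call. The 9 that lost it were neutrophils (1.00, 0.0677), macrophages (0.46, 0.0771), erythrocytes (0.69, 0.226), acute phase (0.48, 0.0914), inflammatory cytokines (0.64, 0.118), luteal cells (−0.90, 0.0556), matrix (0.30, 0.119), fasting (0.43, 0.0684) and circadian clock (−0.14, 0.271). With a term for these libraries 11 of 15 kept their call, and inflammatory cytokines (0.36, 0.18), luteal cells (−0.53, 0.0589), proliferation (0.13, 0.31) and circadian clock (−0.15, 0.111) lost it. Centred over the libraries, the erythrocyte level separated the day 7 groups fully, at −0.9 to 0.608 in controls and 0.963 to 1.727 in DSS. It is thus confounded with DSS, and a call lost with it does not show a cause. With the erythrocyte level in the model 7 of 15 kept their call. Besides interferon genes, oocytes (0.40, 0.0575), sterol synthesis (−0.34, 0.0678), luteal cells (−0.25, 0.245), proliferation (0.19, 0.23), fasting (0.21, 0.11) and circadian clock (−0.08, 0.245) lost it, and the erythrocyte list cannot be tested against its own level.

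Over all 18006 genes, 6 differed between DSS and control ovaries at day 7 with limma, 1 higher and 5 lower, and 2889 (16%) had an unadjusted p under 0.05, while voom on the recovered reads called 0. The single rise was Gm10131, at 32.8 ± 3.74 against 14.7 ± 1.37 FPKM. The falls were Prcd, a photoreceptor disc gene (9.69 ± 1.09 against 24.2 ± 6.43), Srcin1, a regulator of Src kinase (2.11 ± 0.344 against 5.28 ± 0.839), Gm36738, Gm12490 and 9330104G04Rik. The predicted and unnamed genes here fall outside the naming rule. The next smallest p-values among rises belonged to Bpifb4 (log2 fold change 2.26), Mlf1 (1.26) and Sp2 (1.09), and among falls to Cmc2 (−1.02), Cav3 (−1.03) and Upp2 (−0.88). These did not pass, with adjusted p between 0.0638 and 0.0777. The count of 6 depended on single libraries: it was 1221 without DSS replicate 75, 41 without control replicate 10 and 0 without DSS replicate 80, and 1 to 14 without any 1 other sample. Without the 3 libraries of high mitochondrial share it was 915, with a single control left, and 20 with a term for them. With sample weights, estimated from the same data, it was 7133. It was 0 with only the compared samples, with the luteal level or with the erythrocyte level in the model. Each of these levels separates the day 7 groups fully.

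**Figure D2:**
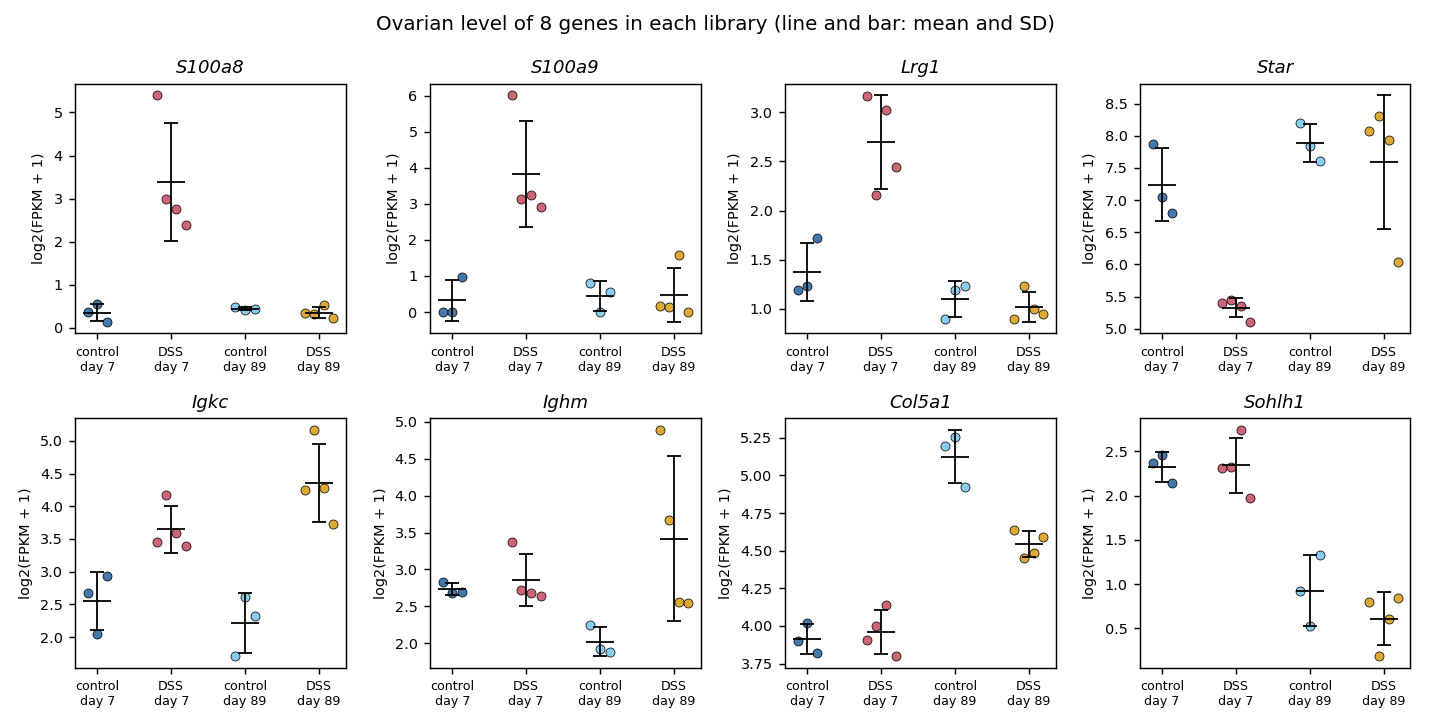
Level of 8 genes, as log2(FPKM + 1), in each of the 14 libraries by group. Points are libraries and bars the mean and SD. S100a8, S100a9 and Lrg1 were highest in DSS day 7, Star was lowest there, Igkc was higher in DSS than in control at day 89 in every library, and Sohlh1 was lower in all day 89 libraries than in all day 7 libraries.

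At day 89 the gene with the smallest p among named genes was Igkc, the constant region of the immunoglobulin kappa chain. Igkc averaged 20.9 ± 9.78 FPKM in DSS (SD, n = 4) and 3.79 ± 1.43 in controls (n = 3), a log2 fold change of 2.15 (SE 0.32). All 4 DSS libraries (12.3 to 35 FPKM) exceeded all 3 controls (2.26 to 5.09), though the adjusted p over all genes was 0.116 with limma. The B and plasma cell list rose by a mean of 0.81, with 9 of 10 members above 0 (camera adjusted p = 7.92e-06; adjusted p = 0.0205 with an estimated correlation). Igkc and Ighm, the mu heavy chain, rose when adjusted over the list alone. Ighm averaged 12.5 ± 11.3 against 3.08 ± 0.574 FPKM, and replicate R29 held the highest value (28.7). Igha, the alpha heavy chain, stood at 4 ± 2.63 against 0.917 ± 0.726, with replicate R29 at 0.38, below all 3 controls. T and NK cell genes differed by 0.11 (adjusted p = 0.362).

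Extracellular matrix genes were lower in DSS than in control ovaries at day 89. The list fell by 0.40, with 20 of 23 members below 0 and 6 fallen when adjusted over the list alone (adjusted p = 1.01e-08; adjusted p = 0.0205 with an estimated correlation). Col5a1, a fibrillar collagen chain, stood at 22.3 ± 1.4 against 34.1 ± 4.22 FPKM, Loxl2, a collagen crosslinking enzyme, at 18 ± 1.65 against 35.7 ± 4.72, and Col4a1 of basement membranes at 133 ± 12.7 against 216 ± 21.6. None passed over all genes (adjusted p = 0.924). Across genes the DSS effect at day 89 fell with gene length, with a Spearman correlation of −0.26, and DSS replicate R38 stood apart in the length measure. The matrix list differed by −0.37 with each library's length trend removed and by −0.45 without R38, called in both. Periovulatory and cumulus expansion genes fell by 0.42, 10 of 11 below 0 (adjusted p = 1.24e-05; adjusted p = 0.0279 with an estimated correlation). Edn2, an endothelin induced in the follicle at ovulation, stood at 0.658 ± 0.381 against 3.12 ± 2.09 FPKM, and the protease Adamts1 at 11.3 ± 0.831 against 23.9 ± 11.8. These 2 and Adamts4 fell when adjusted over the list alone. The rotation test fry asks another question, whether the list differs from no change rather than from the other genes. It gave these 3 lists an adjusted p of 0.0142 for B and plasma cells and for matrix and 0.0156 for periovulatory genes.

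Further lists were called at day 89 with the preset correlation and not with the estimated one. Complement rose by 0.38 (adjusted p = 0.000155; adjusted p = 0.497 with an estimated correlation) and macrophage genes by 0.29 (adjusted p = 0.00562; adjusted p = 0.559 with an estimated correlation). C1qb was 136 ± 64 against 68.7 ± 19.5 FPKM. Interferon-response genes rose by 0.21, 21 of 24 above 0 (adjusted p = 0.000473; adjusted p = 0.559 with an estimated correlation). Without control replicate R126 the interferon list differed by 0.07 and the macrophage list by 0.15, neither called, and complement by 0.24, still called. The interferon list differed by 0.32 without control R123 and by 0.13 without DSS R38, called in both. Erythrocyte genes rose by 1.12 (adjusted p = 0.000166; adjusted p = 0.497 with an estimated correlation), and by 0.68, still called, without DSS R89. Mitochondrially encoded genes rose by 1.01 (adjusted p = 0.00107; adjusted p = 0.559 with an estimated correlation), and by 0.46, not called, without control replicate R124. Heat shock and immediate-early genes fell by 0.20 (adjusted p = 0.0291; adjusted p = 0.559 with an estimated correlation), a call lost without control replicate R124 (−0.02), DSS R78 (−0.18) or DSS R89 (−0.17). It differed by −0.35, called, without control R123. With the luteal level in the model 8 of the 9 lists called at day 89 kept their call. Oocyte genes had a mean of 0.16 (adjusted p = 0.301), which turned to −0.28 and was called without control replicate R124. Luteal genes had a mean of −0.26 (adjusted p = 0.301), sterol synthesis −0.02 (adjusted p = 0.994), primordial follicle reserve −0.04 (adjusted p = 0.385) and neutrophil genes 0.16 (adjusted p = 0.385).

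Over all genes, 1 of 18006 differed at day 89 with limma and 824 (4.6%) had an unadjusted p under 0.05, while voom on the recovered reads called 0. It was Gm49592, a processed pseudogene named outside the rule. It was listed at 0 in all controls, and 3 or 4 reads lay behind each DSS value. The call was lost in 5 of the fits that left out 1 library (control R124 or R126, DSS R29, R38 or R78). With sample weights 92 genes passed. Other leading rises were Bckdhb (log2 fold change 0.49), Klf15 (0.59), Ifi207 (0.88) and Cdhr5 (0.72), and falls Mir5100 (−1.79), Angptl4 (−0.76) and Adamts9 (−0.84), none past the threshold (adjusted p from 0.466 to 0.924). Mir5100 is a short microRNA gene listed at 0 in DSS R29, R38 and R78, so few reads lie behind its values.

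**Figure D3:**
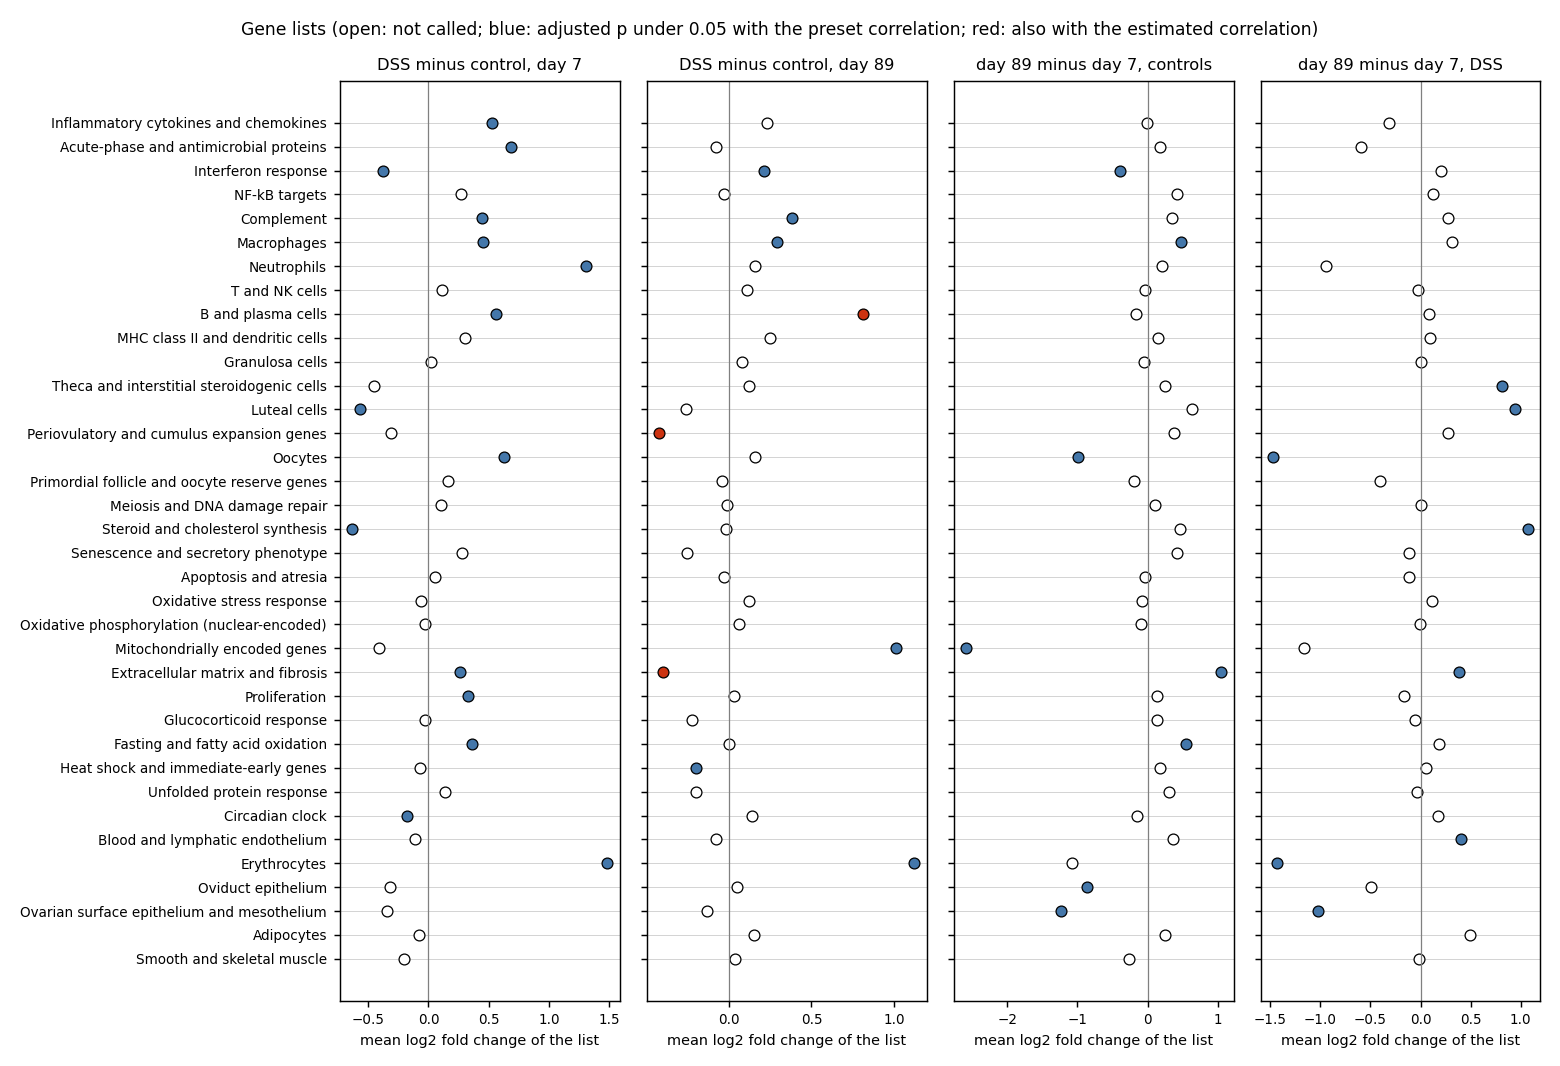
Mean log2 fold change of each of the 36 gene lists in 4 comparisons, 1 panel each. Open circles were not called, blue ones passed adjusted p 0.05 with the preset correlation, and red ones also with the estimated correlation. B and plasma cells (0.81), periovulatory genes (−0.42) and extracellular matrix (−0.40) in DSS against control at day 89 are the red points.

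Day 89 ovaries differed widely from day 7 ovaries, in controls and in DSS. Oocyte genes were lower at day 89. In controls the list fell by 0.99, with 11 of 23 members fallen over all genes (adjusted p = 0.000349; adjusted p = 0.833 with an estimated correlation), and by 0.56, still called, without control day 89 replicate R124. In DSS it fell by 1.47, with 21 of 23 fallen (adjusted p = 2.2e-12; adjusted p = 0.469 with an estimated correlation). Sohlh1, a transcription factor of early oocytes, went from 4.02 ± 0.564 to 0.948 ± 0.541 FPKM in controls and from 4.16 ± 1.14 to 0.546 ± 0.298 in DSS. Ooep in controls had a log2 fold change of −2.20 (SE 0.39), and Figla in DSS −1.56 (SE 0.22). Surface epithelium and mesothelium genes fell by 1.23 in controls (adjusted p = 0.000706; adjusted p = 0.717 with an estimated correlation) and by 1.02 in DSS (adjusted p = 0.000185; adjusted p = 0.486 with an estimated correlation). Msln, the mesothelial protein mesothelin, went from 7.41 ± 1.48 to 1.09 ± 0.442 FPKM in controls. Matrix genes rose in both, by 1.04 in controls (13 of 23 risen; adjusted p = 7.31e-07; adjusted p = 0.0904 with an estimated correlation) and by 0.38 in DSS (7 risen, 1 fallen; adjusted p = 0.00336; adjusted p = 0.400 with an estimated correlation). Col4a1 went from 52.6 ± 13.4 to 216 ± 21.6 FPKM in controls.

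Some lists passed between days in 1 treatment and not in the other, which by itself shows no difference between treatments. In DSS the sterol synthesis list rose by 1.07 (10 of 19 risen; adjusted p = 1.12e-06; adjusted p = 0.486 with an estimated correlation). Luteal genes rose by 0.94 (7 of 16; adjusted p = 0.0058; adjusted p = 0.400 with an estimated correlation), theca genes by 0.81 (adjusted p = 0.0107; adjusted p = 0.317 with an estimated correlation) and endothelial genes by 0.40 (adjusted p = 0.0058; adjusted p = 0.400 with an estimated correlation). Star went from 39.2 ± 3.96 to 223 ± 110 FPKM. Erythrocyte genes fell by 1.43 (adjusted p = 0.00336; adjusted p = 0.486 with an estimated correlation). The values in controls were 0.46 for sterol synthesis, 0.63 for luteal, 0.24 for theca, 0.36 for endothelial and −1.07 for erythrocyte genes. In controls, mitochondrially encoded genes fell by 2.58 (adjusted p = 0.000706; adjusted p = 0.735 with an estimated correlation), where 2 of the 3 day 7 controls held the high mitochondrial share. Oviduct epithelium genes fell by 0.86 (adjusted p = 0.0203; adjusted p = 0.434 with an estimated correlation) and interferon genes by 0.39 (adjusted p = 0.0326; adjusted p = 0.843 with an estimated correlation). Fasting genes rose by 0.54 (adjusted p = 0.01; adjusted p = 0.434 with an estimated correlation) and macrophage genes by 0.47 (adjusted p = 0.0433; adjusted p = 0.717 with an estimated correlation). The values in DSS were −1.16 for mitochondrially encoded, −0.49 for oviduct, 0.20 for interferon, 0.18 for fasting and 0.31 for macrophage genes. The difference between treatments did not pass for luteal (adjusted p = 0.219), endothelial (0.998), erythrocyte (0.269), oviduct (0.139) and macrophage genes (0.153). The macrophage call was lost with only the compared samples in the fit (adjusted p = 0.0642), scaled to each library's own read total (0.0537) and without control day 7 replicate 10 (0.44), DSS day 7 replicate 75 (0.47), control day 89 R123 (0.35) or R124 (0.46), or DSS day 89 R38 (0.47), and the interferon call without control day 89 R126 (−0.25) or scaled to each library's own read total (−0.31, adjusted p = 0.0504). Gpnmb, a macrophage glycoprotein, went from 2.89 ± 0.2 to 18 ± 6.19 FPKM in controls.

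Alternatives ended several of these calls between days. In controls without the 3 libraries of high mitochondrial share 3 of 8 lists kept their call. Mitochondrially encoded genes (−0.50, adjusted p = 0.452), oocytes (−0.64, 0.0856), oviduct epithelium (−0.76, 0.0781), interferon (−0.34, 0.123) and macrophages (0.49, 0.167) lost it. In controls the luteal and the erythrocyte level each separate the days fully, so both covariates are confounded with day there. With the luteal level in the model 5 of 8 kept their call in controls, and oocytes (−0.46, 0.193), surface epithelium (−0.77, 0.0649) and macrophages (0.37, 0.27) lost it. In DSS it was 1 of 8, the oocyte list. Sterol synthesis (0.33, 0.54), surface epithelium (−0.34, 0.536), erythrocytes (−0.55, 0.536), theca cells (0.41, 0.283), endothelium (0.26, 0.266) and matrix (0.42, 0.0522) lost it, and the luteal list cannot be tested against its own level. With the difference between short and long genes as a covariate 4 of 8 kept their call in controls, and interferon (−0.09, 0.672), mitochondrially encoded (−0.27, 0.672), fasting (0.28, 0.116) and oviduct genes (−0.37, 0.235) lost it. In DSS 6 of 8 kept it, and sterol synthesis (0.37, 0.127) and endothelium (0.26, 0.131) lost it. The short against long measure separates the days fully in controls and in DSS, so it is confounded with day in both. At day 89 the same covariate ended the calls of mitochondrially encoded (0.50, 0.151) and heat shock genes (−0.08, 0.248) for DSS against control. With the erythrocyte level in the model luteal genes (0.63, 0.0612) and surface epithelium (−0.53, 0.0982) lost their call in DSS, and macrophages (0.37, 0.142) in controls.

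In controls 5732 genes differed between days, 2900 higher and 2832 lower, and in DSS 3860, 1925 higher and 1935 lower. The largest rises in controls were Vcl (vinculin, log2 fold change 3.82), Mmp2 (3.12), Adcy9 (2.87), Mir1898 and Pcdhgc3, and the largest falls Mir3092 (−4.61), a 5S_rRNA copy, Mir99a, a U1 copy and Mir6929. In DSS they were Mir186 (3.38), Vcl (2.67), AU021092, Cpxm2 and Inhba, and S100a9 (−3.35), Rn7sk, S100a8 (−3.03), Mir99a and mt-Tl2. Mir186 is a short microRNA gene at 0, 0.776, 0.744 and 0 FPKM in DSS day 7, so few reads lie behind its low values. Genes called higher in both controls and DSS numbered 1402, where independent lists would share 310, and lower in both 1281, where they would share 304.3. These comparisons share no libraries but share the day, and day, age and any batch between days cannot be separated. Genes that rose in controls had a median length of 6251 bases and those that fell 2625. Across genes the fold change followed length with a Spearman correlation of 0.42 in controls and 0.40 in DSS, and genes are not independent replicates. With the difference between short and long genes as a covariate the count was 0 in controls and 93 in DSS. In controls that measure separates the days fully (0.148 to 0.359 at day 7 and −0.326 to −0.283 at day 89). In DSS it does so too (0.163 to 0.341 and −0.329 to 0.13), so the covariate is confounded with day in both. Without the 3 libraries of high mitochondrial share the count in controls was 3231, with a single day 7 control left. The count in controls was 3695 without control day 7 replicate 53, and that in DSS 2034, 2061 and 2510 without DSS day 89 replicate R29, R78 and DSS day 7 replicate 81. With the erythrocyte level in the model the count in DSS was 1146, and with the luteal level 1761. With sample weights the counts were 11786 in controls and 7956 in DSS.

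The DSS effect itself differed between days for matrix genes as a list, which were 0.66 lower in the day 89 effect than in the day 7 effect, 21 of 23 below 0 (adjusted p = 6.29e-09; adjusted p = 0.0426 with an estimated correlation). Of these, 7 differed when adjusted over the list alone, among them Fn1, fibronectin (−1.19, SE 0.28), and Col4a2 (−1.16, SE 0.28). No single gene of 18006 passed for this difference with limma, while 1521 (8.4%) had an unadjusted p under 0.05 and voom on the recovered reads called 0. Without DSS day 7 replicate 75, 41 genes passed, and with sample weights 4226. The smallest p-values belonged to Srcin1 (1.31), Bckdhb (0.89), Ifit3b (1.20), Prcd (1.25) and AU021092 (2.02), and to Angptl4 (−1.34), Cd276 (−0.98), Gpr153 (−1.16), Nfil3 (−1.37) and Gpc1 (−1.79). Across genes the DSS effects at both days had a Pearson correlation of 0.14 and a Spearman correlation of 0.12. The error from leaving out each library was 0.32, and the Pearson correlation was 0.5 with the erythrocyte level in the model. No gene was called in the same direction at both days. With 6 genes called at day 7 and 1 at day 89, independent lists would share 0 too, so this decides nothing.

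On GRCm38, in the GENCODE M21 annotation, S100a8 lies on chromosome 3 from 90668978 to 90670035 and S100a9 beside it from 90692632 to 90695721. Star lies on chromosome 8 from 25806555 to 25815982, Prcd on chromosome 11 from 116653534 to 116668389 and Srcin1 on the same chromosome from 97509340 to 97576186. Igkc lies on chromosome 6 from 70726435 to 70726966 and Ighm on chromosome 12 from 113418558 to 113422730. Col5a1 lies on chromosome 2 from 27886425 to 28039514 and Sohlh1 on chromosome 2 from 25842995 to 25847248.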

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

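The tests of the 3 libraries with high mitochondrial share and of attached lymphoid tissue, and every alternative with a mitochondrial term, an erythrocyte level or a length trend, were chosen only after the results had been seen.

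In groups of 4, a library was singled out when its gap to the nearest other, divided by the range of the group, exceeded Dixon's critical value at 95%. For genes the ratio was taken on log2(FPKM + 1), while the values printed are FPKM. Of 93 values tested 13 met this, where chance singles out about 1 in 20, or 4.7. The values come from the same libraries and are not independent, so 4.7 is only a rough reference. In DSS day 7, replicate 75 stood apart for S100a9 (63.9 FPKM against 6.54 to 8.4 in the others, gap ratio 0.897), Mmp2 (3.15 against 10.9 to 13.5, 0.84), Aurkb (5.24 against 11.4 to 12.5, 0.893) and the mitochondrial share (14.2% against 3.48% to 4.04%, 0.948). Replicate 81 stood apart for Bpifb4 (27.5 against 38.8 to 39.4, 0.959), replicate 80 for Srcin1 (1.6 against 2.21 to 2.34, 0.842) and replicate 82 for Gbp3 (8.41 against 5.29 to 5.46, 0.936). In DSS day 89, replicate R38 stood apart for mt-Cytb (6370 against 3390 to 3750, 0.837), Hsph1 (7.47 against 13.1 to 14.4, 0.85), the mitochondrial share (3.66% against 2.37% to 2.57%, 0.845) and the level of short against long genes (0.13 against −0.329 to −0.268, 0.867). Replicate R89 stood apart for mt-Nd4l (57.7 against 20.4 to 24.4, 0.831) and Mir5100 (0.884 against 0, ratio 1). For Mir5100 the ratio is fixed at 1 because all other values are 0, and few reads lie behind 0.884 FPKM of so short a gene.

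For 13 lists the DSS effect at day 89 differed from that at day 7 in a test of the difference itself. The effect was higher at day 89 for interferon response (mean 0.59, adjusted p = 6.92e-10), sterol synthesis (0.61, 0.000479), mitochondrially encoded genes (1.42, 0.00532), circadian clock (0.32, 0.011) and theca cells (0.57, 0.0278). It was lower for extracellular matrix (−0.66, 6.29e-09), oocytes (−0.47, 0.0064), fasting (−0.36, 0.00686), senescence (−0.53, 0.0156), proliferation (−0.30, 0.0173), unfolded protein response (−0.34, 0.0278), acute phase (−0.77, 0.0289) and neutrophils (−1.15, 0.0453). With an estimated correlation the matrix list alone passed (adjusted p = 0.0426), and the others lay between 0.222 and 0.675. The calls for matrix, interferon, sterol and circadian genes held when each library was left out, and each of the other 9 lists lost its call without at least 1 library. Of the 13 calls, 11 were kept with the luteal level in the model and 11 with voom. The short against long covariate kept 10, and the term for the 3 libraries of high mitochondrial share kept 9. Without the 3 libraries of high mitochondrial share the mitochondrially encoded list differed by −0.07. Chance was not excluded for this number of lists: 13 of 100 splits gave as many, the real split included, and the highest other gave 19. For single genes the splits decide nothing, because the real count was 0 and each of the 100 splits calls at least 0 genes (highest other 409).

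Neutrophil transcripts stood higher in DSS ovaries at day 7, with a list median of 0.66, though the list was not called with an estimated correlation (camera adjusted p = 0.292). Some members passed the filter only through DSS day 7 libraries. The mean log2 difference was 1.31 (SE 0.30) and with the erythrocyte level in the model 1.43 (SE 0.42). That level separates the day 7 groups fully, so the adjusted value rests on a slope fitted within the groups. It argues against more blood as the whole of the rise only if that slope holds between them. Without DSS replicate 75 the difference was 0.97 (SE 0.11), but the filter that chose the members had counted that library, and Retnlg passed only with it. The list mean therefore cannot decide about a single library. S100a9 also reached 0.5 FPKM in control day 7 replicate 53, control day 89 R123 and DSS day 89 R78. Its log2 fold change without replicate 75 was 2.77 (SE 0.39), which argues against a single library for that gene. More neutrophils per volume of blood, and neutrophils in the tissue, stay open, since the erythrocyte level measures neither.

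B and plasma cell transcripts stood higher in DSS ovaries at day 89. The difference was 0.81 (SE 0.16), and 1.05 (SE 0.14) with the erythrocyte level in the model. That level raised the difference, through a slope shared by all groups, so the adjusted value does not model transcripts brought by blood. Centred over the libraries, the erythrocyte level of DSS R29 (−1.257) lay among the controls (−1.358 to −1.214). Its B and plasma cell level was 0.55, against −0.523 to −0.427 in controls, which argues against more blood in R29. In R38, R78 and R89 the erythrocyte level exceeded the controls, and more blood stays open there. Attached lymphoid tissue would bring T cells too, and T and NK cell genes differed by 0.11 (SE 0.13), with 11 of 20 listed genes measured. Their centred level was above the controls (−0.183 to −0.016) in R29 and R38 (0.172 and 0.102). It lay among the controls in R78 and R89 (−0.099 and −0.049). The group difference therefore decides nothing about attached lymphoid tissue in R29 and R38. Xbp1, which plasma cells need but which stood at 50.1 ± 6.45 FPKM in controls already, was 45.4 ± 5.39 in DSS. The kind of cell behind the immunoglobulin transcripts, more B or plasma cells per volume of blood, and differences in housing or dissection, stay open.

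Many genes differed between days. A trend shared by all genes of a length is argued against as the whole cause, since 4865 genes differed in controls after each library's trend with length was removed, and a GC trend likewise (5866). With the difference between short and long genes as a covariate 0 genes differed in controls and 93 in DSS. Since that measure separates the days fully in controls and in DSS, a library property that goes with it stays open in both. Of the 3 libraries of high mitochondrial share, only DSS day 7 replicate 75 belongs to the DSS comparison between days. With the 3 libraries left out 3268 genes differed in DSS, which argues against that replicate as the whole cause there. Control day 7 replicates 10 and 53 are not part of that comparison, so it decides nothing about these libraries in controls. Age and any batch between days cannot be told apart, because each day holds its own libraries.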

How the results depend on the processing

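The alternatives with a mitochondrial term or without the 3 libraries, with an erythrocyte or short against long gene covariate, with a length or GC trend removed, scaled to the own read total or with voom were added after the results had been seen. No paired analysis was possible because the groups share no replicate numbers. The planned count test and its size factors were not run, because the unit is FPKM, and the planned log2(FPKM + 1) alternative is the reported setting; the correlation was not computed without a filter or with only the compared samples. Where not said otherwise, the cause was not tested. At day 7 the luteal and the erythrocyte level each separate the groups fully, so these covariates are confounded with DSS there. Genes called at day 7 (6 as reported) numbered 2 with a mean FPKM of at least 1, with a pseudocount of 0.1 and scaled to own read totals, 1 at adjusted p 0.01, 0 with only the compared samples (fewer samples), the luteal or erythrocyte covariate and voom, 11 with the length trend removed, 30 with the short against long covariate, 20 with the mitochondrial term and 915 without the 3 libraries. At day 89 (1 as reported) they numbered 5 without a filter and 0 with a mean FPKM of at least 1, pseudocount 0.1, only the compared samples, adjusted p 0.01, a log2 fold change of at least 1, without the 3 libraries, the erythrocyte or short against long covariate, the length trend removed and voom. Between days, controls gave 2805 at adjusted p 0.01, 2089 at a log2 fold change of at least 1 (both stricter by construction), 3231 without the 3 libraries, 3141 with the mitochondrial term and 0 with the short against long covariate, which separates the days fully in controls. DSS gave 1180 and 910 at the stricter thresholds, 1761 with the luteal, 1146 with the erythrocyte and 93 with the short against long covariate. The short against long covariate separates the days fully in DSS too. For the difference between DSS effects there were 2 genes without a filter and 3 without the 3 libraries. Sample weights gave 7133 and 92 genes for DSS against control at days 7 and 89, 11786 and 7956 between days in controls and DSS, and 4226 for the difference; they ran from 0.21 for DSS day 7 replicate 75 to 5.4 for control day 7 replicate 53. Lists called with an estimated correlation were 0 at day 7, 3 at day 89, 0 in controls and 0 in DSS between days and 1 for the difference, and with fry 0, 3, 9, 9 and 1 in that order. Without the 3 libraries 6 lists were called at day 7, 4 in controls between days and 7 for the difference. With the erythrocyte covariate 9 were called at day 7 (7 of the 15 reported among them), and between days in DSS 2 with the luteal covariate (1 of the 8 reported) and 15 with the short against long covariate (6 of 8). The correlation of DSS effects was 0.5 with the erythrocyte covariate. Leaving out each library in turn gave 0–1221 genes at day 7, 0–2 at day 89, 3695–6463 and 2034–4930 between days in controls and DSS and 0–41 for the difference. It gave 12–19, 8–12, 7–11, 8–13 and 6–15 lists in that order, and a correlation of −0.07 to 0.26. Among genes and lists that passed as reported or under the alternative, the direction of the test turned in 8 cases: at day 7 granulosa genes with the luteal covariate (−0.33), proliferation with it (0) and mitochondrially encoded genes with the mitochondrial term (0.72); at day 89 oocyte genes without control replicate R124 (−0.28, and up to 0.38 without another library) and sterol synthesis with the short against long covariate (0.19). With that covariate proliferation (−0.54), Mir99a (0.17) and Cfap126 (0.11) turned between days in controls. In 2 more lists the mean changed sign while the test's direction against the other genes held: mitochondrially encoded genes for the difference without the 3 libraries (−0.07) and muscle genes between days in DSS with the short against long covariate (0.47). Of the other values for named genes, alternatives set beforehand left 3671 on their side of the threshold, 141 stronger and 72 weaker, and added ones 1239, 37 and 74. For lists these were 2966, 100 and 166, and 1333, 43 and 56. Quantile normalization and the GC trend removed moved no count of genes by over 1.5 times.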

Other observations

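The tests added after the results had been seen are named in the first part, and the genes in this part were chosen after their values were seen.

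Ccl8, a chemokine that draws monocytes, averaged 20.7 ± 11.4 FPKM in DSS ovaries at day 7 (SD, n = 4) and 1.82 ± 0.801 in controls (n = 3), a log2 fold change of 2.83 (SE 0.57). Over all genes its adjusted p was 0.0814 with limma, and it rose when adjusted over the list of senescence genes alone (0.00347). Trp53, which encodes p53, stood at 28.7 ± 10.5 against 12.9 ± 5.93 FPKM and also rose when adjusted over that list alone (0.0167). At day 89 Ccl8 stood at 4.2 ± 4.73 in DSS and 2.39 ± 1.36 in controls. DSS replicate R38 alone held 11.1, and the other DSS libraries lay between 0.554 and 2.87. As a whole the senescence list was not called at day 7 (mean 0.28, adjusted p = 0.101).

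Single stress and clock genes differed between days, though their lists were not called (adjusted p in controls and DSS: unfolded protein response 0.306 and 0.831, oxidative stress 0.996 and 0.646, circadian clock 0.547 and 0.369). Atf4, a transcription factor of the stress response, fell by 1.25 in controls (limma adjusted p = 0.000523) and by 0.73 in DSS (0.00687). Calr, a chaperone of the endoplasmic reticulum, rose by 1.31 and 0.69 (0.00275 and 0.0437), and the clock gene Arntl by 1.16 and 0.56 (0.000954 and 0.0265). Gpx1, which reduces peroxides, fell by 1.97 in controls (0.00331), and its value in DSS was −0.91 (0.0792). Among genes of the primordial follicle reserve, a list not called between days in controls or in DSS, Figla fell by 1.06 and 1.56 (0.0074 and 0.0015).

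Other splits of the same libraries show how far chance can be excluded. For DSS against control at day 7, 3 of 35 splits called at least the real 6 genes, so chance was not excluded. The highest other split called 1615, which points to a structure of the samples: it set DSS replicates 80, 81 and 82 against the rest. The split that follows the mitochondrial share, replicates 10, 53 and 75 against the rest, called 1432, and with a term for that share the real split called 20. For lists 6 of 35 splits reached the real 15, with 16 in the highest other.

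At day 89, 20 of 35 splits called at least the real 1 gene (highest other 33) and 13 of 35 at least the real 9 lists (highest other 15), so chance was not excluded for either. For days within DSS, 1 of 35 splits, the real one, reached 3860 genes against 3 in the highest other. The real split thus stood alone, and 1 of 35 is the smallest share these splits can give. Every other split mixes both days in each group, which widens the spread within groups and lowers its count. Chance was not excluded for the lists, where 17 of 35 splits reached the real 8 and the highest other gave 19. For days within controls the 10 splits are too few: the real split called 5732 genes and the highest other 1, and the real split called 8 lists, which 4 splits reached, and the highest other 9.

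Leaving DSS replicate 75 out of the day 7 comparison gave 1221 genes, 624 higher and 597 lower, among them all 6 called with it. All 1221 had the same direction with it included, and 975 had an unadjusted p under 0.05 there. Both fits share every other library, so this agreement is largely fixed in advance. The DSS libraries left at day 7 are replicates 80, 81 and 82, whose split against the rest called 1615 genes. The count of 1221 therefore does not separate DSS from whatever else these replicates share. S100a8 then had a log2 fold change of 2.36 (SE 0.17, limma adjusted p = 7.67e-05) and S100a9 of 2.77 (SE 0.39, 0.00507). With an estimated correlation 0 lists were called. The labels give no reason to leave this library out, and it was chosen after its values were seen.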
